A study of Mus musculus with 6 samples.

How the data were processed

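Bulk RNA sequencing was performed on epithelial cells isolated from the ileum of mice, with 3 control libraries (floxed Ogt) and 3 Ogt knockout libraries (floxed Ogt with Olfm4-CreER). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit, which does not mark the strand, so reads of overlapping antisense genes cannot be told apart. The submitters' processing notes name the genome builds GRCm39 and mm39. The aligner, the counting tool, the annotation release and any filter are not given in the sources used here. The authors deposited 1 table of 22274 genes with, per library, estimated counts (expected counts) and FPKM values, per the file headers. Between 7.68% and 8.09% of the deposited estimated counts per library were not whole within a tolerance of 0.001, as happens when reads of similar genes are shared out. The deposited FPKM values were scaled by the authors for transcript length and library total, and the lengths used are not stated in the file headers.

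Estimated counts were rounded to whole numbers. Library totals ranged from 14389435 to 18076484 counts. With library sizes scaled by the TMM factors, 3 counts in a library correspond to between 0.159 and 0.207 CPM. All 22274 rows name a gene. Gene names were taken by Ensembl ID from GENCODE M21, an annotation of an older build used here for names, gene types and gene order only (22219 IDs), then from the deposited table (44 IDs), and 11 IDs kept no name. Of 41 rows that shared a symbol with a row of more counts, the ID was added to the name. No 2 libraries agreed within sampling noise: the mean chi-square per gene was at least 20.6 for every pair, against 1 for sampling alone.

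Genes were kept with the filterByExpr function of edgeR (minimum count 10, minimum total 15), libraries were scaled with TMM factors and Ogt knockout was compared with control by the quasi-likelihood test with robust dispersion (edgeR 4.0.16, R 4.3.3). P-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05, and the SE of a log2 fold change was taken from its F statistic. CPM values are normalised with the TMM factors. The groups, the test, 44 gene lists (32 of biology and 12 of other cell types and library checks) and the alternatives were fixed before the data were examined. Lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 44 lists, and again with an estimated correlation and with fry. None of the 9 list calls held with an estimated correlation. That setting also tests on the few residual degrees of freedom of the libraries, so a lost call does not by itself show correlated genes. The tuft cell list lost its call at an estimated correlation of 0.0021, below the preset one. Of the list members 6 had no match by name and 8 were matched through a synonym.

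The genes named in the text follow a rule fixed beforehand: Ogt, Oga and Olfm4; the 8 largest increases and 8 largest decreases past the threshold with a mean log2 CPM of at least 1, groups that do not overlap and a name other than a predicted gene; and, per list, the 3 genes with the smallest adjusted p and the most abundant gene (1 and the most abundant for lists of other cells). Of the genes this rule gives, 1 is not described. Further genes in the text (Amdhd2, Nagk, Trpm5, Pou2f3, Slc15a1, Rps6kb1, Gars1 and those of the closing part) were chosen after their values were seen. Groups did not overlap for 39.84% of the tested genes, where chance gives 10%.

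The test was run on simulated counts for the 14005 genes of this comparison, drawn from their means and library sizes with 200 genes changed. It recovered 55 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, none in the wrong direction, with 15 false calls, a larger share of its calls than the threshold sets, and called 0 genes when none was changed. Camera called a simulated list lowered 4-fold and 0 of 40 unchanged lists, with either correlation. The simulated genes were drawn independently, so this could not test lists whose genes move together. In the real data the estimated correlation was 0.90 for cytosolic ribosomal proteins and 0.82 for proliferation, against 0.002 for tuft cell genes. The alternatives were DESeq2 size factors, library size alone and upper quartile factors; DESeq2 1.42.0 and limma voom; no count filter and a minimum of 1 CPM in 3 libraries; the replicate number as a block; each library left out in turn; limma on log2(FPKM + 0.1) and log2(FPKM + 0.01) for genes of at least 1 FPKM in 3 libraries, and a minimum of 5 FPKM; a log2 fold change of at least 1; removal of the 20 most abundant genes; and protein-coding genes only. The level of the Paneth cell list as a covariate and limma on log2(FPKM + 1) were added after the data had been seen. Ratios for genes with few counts carry exact binomial (Clopper-Pearson) 95% intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.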

Results

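RNA was sequenced from intestinal epithelial cells isolated from the ileum of mice in 2 groups of 3 libraries. In the Ogt knockout group, the Olfm4-CreER driver, a tamoxifen-inducible recombinase expressed from a gene of crypt stem cells, was combined with floxed alleles of Ogt. Ogt encodes O-GlcNAc transferase, the enzyme that attaches single N-acetylglucosamine residues to nuclear and cytoplasmic proteins. The control group carried the floxed alleles, and no driver is given for it. Effects of the driver or of recombinase activity therefore cannot be told apart from effects of losing Ogt. Tamoxifen was given on 3 consecutive days at 2 months of age and tissue was collected on day 10. Each library held between 14389435 and 18076484 estimated gene counts, and 14005 of the 22274 listed genes had enough counts to be tested. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples. The comparison asks which transcripts differ in ileal epithelium after loss of Ogt, in a study whose title links the enzyme to epithelial homeostasis, repair and mTORC1, a protein complex that couples growth to nutrients.

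Ogt itself fell in every knockout library, from 132 ± 7.21 CPM (counts scaled to library size; mean ± SD, n = 3) in control to 42.5 ± 6.26 CPM in knockout libraries. The log2 fold change was -1.63 ± 0.13 (± SE here and below; adjusted p = 0.00121). The position of the floxed part within Ogt is not given in the labels used here, so reads from the rest of the transcript could still count. Neither this nor any other source of the remaining Ogt reads was tested. Oga, which encodes the enzyme that removes O-GlcNAc, fell by a similar amount, from 108 ± 8.44 to 39.0 ± 7.14 CPM (-1.47 ± 0.14, adjusted p = 0.00162). Olfm4, the stem cell gene that drives the recombinase, stood at 83.5 ± 54.6 CPM in control and 117 ± 77.3 CPM in knockout libraries and did not pass the test (adjusted p = 0.692). Of the 13 measured genes of O-GlcNAc cycling and hexosamine supply, 3 rose and 2 fell, or 5 and 3 when adjusted over the list alone, without a call for the list (camera adjusted p = 0.966). Pgm3, an enzyme of UDP-GlcNAc synthesis, rose (0.91 ± 0.14), as did Amdhd2 (0.90 ± 0.15) and Nagk (0.62 ± 0.15). Gfpt1, the abundant first enzyme of the hexosamine pathway, stood at 0.32 ± 0.12 and did not pass the test. Leaving out 1 library ended the call of Nagk (control 2 or 3 or each knockout; adjusted p up to 0.0884).

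**Figure D1:**
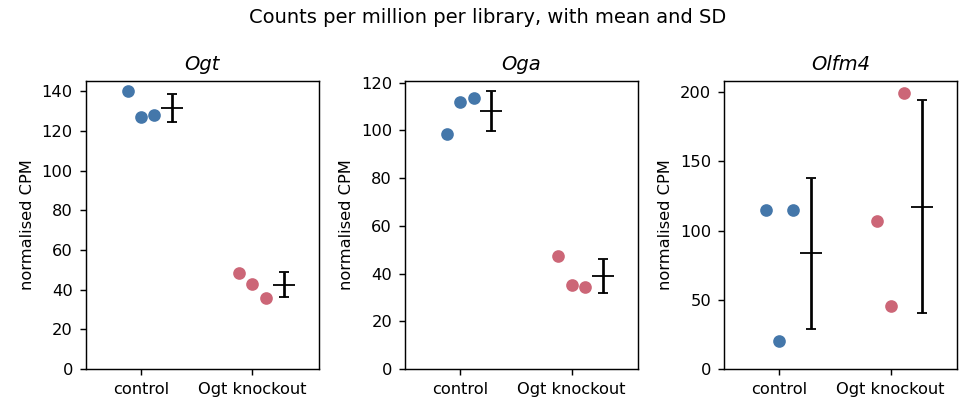
Normalised counts (CPM) of Ogt, Oga and Olfm4 in the 3 control and 3 Ogt knockout libraries; points are libraries, and bars give the mean with its SD. The knockout libraries lie between 36.0 and 48.5 CPM for Ogt, all below the control libraries at 127 to 140 CPM, whereas the Olfm4 values of the 2 groups overlap.

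Of the 14005 genes tested, 2619 (18.7%) changed, 1307 higher and 1312 lower in Ogt knockout libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Numbers of changed list members given below are to be read against these shares. Changes of at least 2-fold made up 270 of the higher and 446 of the lower genes. Among the largest increases were Myot and Acta1, genes of striated muscle, Cyp2b10, a xenobiotic-metabolising cytochrome P450, and Meltf, a transferrin-family protein. Cyp2b10 went from 2.95 ± 2.72 to 65.3 ± 6.45 CPM (4.46 ± 0.61) and Acta1 from 35.0 ± 21.7 to 415 ± 218 CPM (3.57 ± 0.68). Myot had 5 counts over the 3 control libraries and 724 over the knockout libraries, a ratio of 141 with a 95% counting interval of 60.0 to 435. Meltf (5.19 ± 0.42), the complement protease Cfi (3.44 ± 0.37), Tcf24 (3.17 ± 0.39), Tdrd1 (3.10 ± 0.38) and the decoy receptor Tnfrsf23 (3.07 ± 0.43) completed the largest increases. The largest decreases included Pla2g4c, a cytosolic phospholipase A2, from 351 ± 294 to 3.07 ± 0.842 CPM (-6.85 ± 1.17; 34.3 CPM in control 1 against 404 and 615 CPM in the other controls), and Slc47a1, an organic cation exporter (-3.65 ± 0.31). Hao2 (-4.16 ± 0.50), Cyp3a44 (-4.63 ± 0.92) and the tuft cell adaptor Sh2d6 (-3.88 ± 0.51) also fell. The nucleoside transporter Slc28a1 had 198 control and 2 knockout counts, a ratio of 102 with a counting interval of 27.8 to 847. Gsdmc2 (-3.89 ± 0.72), Gsdmc3 (-4.06 ± 0.84) and Gsdmc4 (-2.86 ± 0.51), pore-forming gasdermins, fell as well. Their estimated counts were not whole in any library, so reads shared among these near-identical genes make the split between them uncertain. Cyp3a44 and Cyp2b10 also belong to families of similar genes, but their estimated counts were whole in every library. Those of Tnfrsf23 were not whole in 4 libraries. Intervals cover counting error only. The count of changed genes was 3305 without control 1, and dropped to 1680 without control 2, 1200 without control 3, 1654 without knockout 1, 1134 without knockout 2 and 1010 without knockout 3. Scaling by library size alone moved the median log2 fold change of all genes from -0.05 to 0.09, and the split became 2045 higher and 859 lower genes. Without 1 library the test was not passed by Acta1 (control 1 or 2 or knockout 2; adjusted p up to 0.0723), Pla2g4c (each knockout; adjusted p up to 0.0841), Cyp3a44 (control 2 or 3 or knockout 2 or 3; adjusted p up to 0.0673) and Gsdmc2 (control 1 or knockout 2; adjusted p up to 0.0760). The call was lost without 1 library for Gsdmc3 (each control or knockout 2 or 3; adjusted p up to 0.0845) and Gsdmc4 (knockout 3; adjusted p up to 0.0529).

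**Figure D2:**
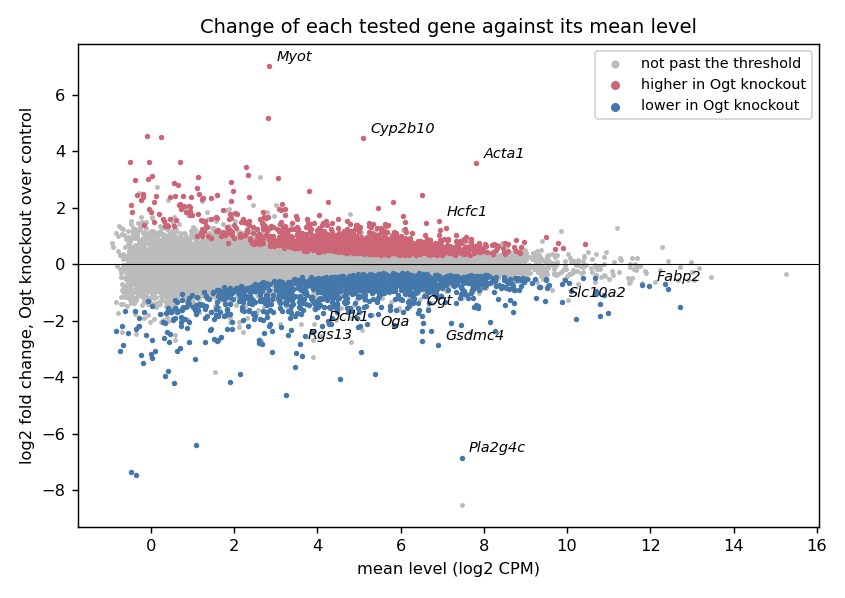
Log2 fold change of each of the 14005 tested genes (Ogt knockout over control) against its mean level in log2 CPM; red points are the 1307 higher genes, blue points the 1312 lower genes and grey points the genes that did not pass the test. Myot, Cyp2b10 and Acta1 stand among the largest increases and Pla2g4c among the largest decreases.

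Tuft cells, the chemosensory cells of the epithelium, showed the largest group change. Of 22 measured tuft cell genes 15 fell and none rose, or 19 when adjusted over the list alone, with a median log2 fold change of -2.16 (camera adjusted p = 8.1e-11; adjusted p = 0.0712 with an estimated correlation). Rgs13 went from 20.9 ± 2.43 to 2.93 ± 0.504 CPM (-2.84 ± 0.19) and Dclk1, a kinase used as a tuft cell marker, fell (-2.20 ± 0.18). Avil (-2.13 ± 0.18), the cation channel Trpm5 (-2.51 ± 0.23) and Pou2f3, the transcription factor that specifies the lineage (-2.19 ± 0.34), fell alike. Cd24a, the most abundant member, which the Paneth cell list also holds, fell by less (-0.74 ± 0.16). The myeloid cell list shares Siglecf (-2.80 ± 0.38), its only member to fall. Between 12 and 16 tuft cell genes passed the test when each library was left out in turn, and 13 passed without control 2. With 1 library left out, no call was made for Cd24a (control 3 or knockout 2; adjusted p up to 0.0689).

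**Figure D3:**
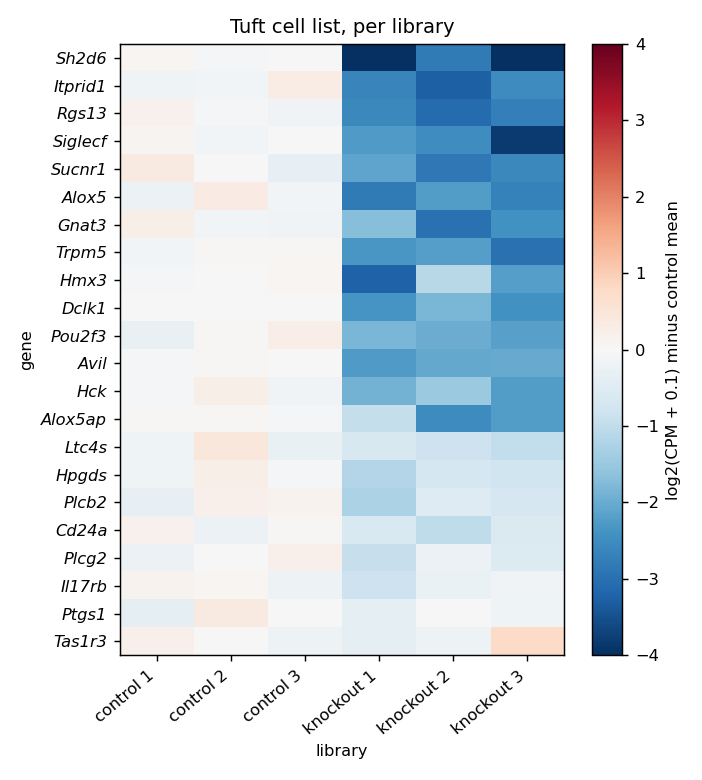
Level of the 22 tuft cell genes in each library, as log2(CPM + 0.1) minus the mean of the 3 control libraries (blue lower, red higher). Most genes are lower in all 3 knockout libraries. The list mean there lies between -1.64 and -1.85 on log2 CPM values with a prior count of 2, a scale other than the one plotted.

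Other secretory lineages had few changed genes. Of 19 goblet cell genes 2 fell and none rose: Zg16, from 2563 ± 1008 to 970 ± 283 CPM (-1.40 ± 0.32), and Clca1 (-1.10 ± 0.27), both secreted into mucus. Fut2 (-2.39 ± 0.80) and the abundant Fcgbp (-0.23 ± 0.43) did not pass the test. Among 21 Paneth cell genes Cd24a and Mptx1 fell, the latter with 66 control counts and 0 knockout counts, at least 7.40-fold lower against a floor of 3 counts per library. Ang4 (-1.90 ± 0.80) and Lyz1 (0.37 ± 0.84) did not pass the test. Paneth cell genes differed widely within the groups: control 2 lay 1.88 log2 units below the control mean, with Lyz1 at 128 CPM against 1553 and 1047 CPM in the other controls. Of 24 enteroendocrine genes 2 rose and 1 fell, or 1 and 0 over the list alone. Ghrl, the precursor of ghrelin, rose from 0.860 ± 0.640 to 6.49 ± 0.727 CPM (2.91 ± 0.53) and secretin, Sct, rose too (0.74 ± 0.21), while the prohormone convertase Pcsk1 fell (-0.50 ± 0.14) and Nts stood at -0.49 ± 0.23. None of these 3 lists was called by camera (adjusted p = 0.902, 0.967 and 0.259). Of the goblet cell genes 6, 0, 0, 0, 0 and 0 were higher and 3, 1, 1, 0, 1 and 0 were lower without controls 1 to 3 and knockouts 1 to 3 in turn. Goblet cell genes were called higher as a list without control 1 (adjusted p = 0.0457). Of the Paneth cell genes 2, 2, 1, 2, 1 and 2 were lower in the same order. Paneth cell genes were called lower as a list without control 2 (adjusted p = 0.00615). Of the enteroendocrine genes 4, 1, 1, 1, 1 and 1 were higher and 2, 0, 0, 0, 1 and 0 were lower in the same order. Calls that ended without 1 library were those of Zg16 (control 2 or knockout 1 or 3; adjusted p up to 0.0875), Clca1 (control 3 or each knockout; adjusted p up to 0.104), Sct (control 2 or 3 or each knockout; adjusted p up to 0.141) and Pcsk1 (control 2 or 3 or each knockout; adjusted p up to 0.168).

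Genes of absorptive enterocytes fell in part. Of 32 members 7 fell and none rose, over all genes and over the list alone, with a median of -0.53 (camera adjusted p = 0.055). The fatty acid-binding protein Fabp2 went from 5101 ± 387 to 2979 ± 352 CPM (-0.78 ± 0.16), and Fabp1 (-1.67 ± 0.26), intestinal alkaline phosphatase Alpi (-0.91 ± 0.16) and the peptide transporter Slc15a1 (-1.46 ± 0.38) also fell. Anpep, the most abundant member, stood at -0.56 ± 0.34 and did not pass the test. Slc10a2, the ileal bile acid importer, fell from 1343 ± 251 to 527 ± 128 CPM (-1.35 ± 0.22), while Abcc3, a basolateral exporter, rose (1.01 ± 0.13). Abcc2 (-0.97 ± 0.38) and the bile acid-binding protein Fabp6 (-0.18 ± 0.15) did not pass the test, and no other of the 11 genes of that list changed. Among 8 genes typical of the proximal small intestine the iron exporter Slc40a1 (-2.21 ± 0.31) and calbindin S100g (-1.67 ± 0.41) fell, and Tfrc stood at -0.41 ± 0.25. Neither of these lists was called (adjusted p = 0.882 and 0.414). Of the enterocyte genes 0, 0, 0, 1, 0 and 0 were higher and 15, 3, 2, 3, 3 and 2 were lower without controls 1 to 3 and knockouts 1 to 3 in turn. Enterocyte genes were called lower as a list without control 1 (adjusted p = 0.000120) or knockout 2 (adjusted p = 0.0227) and with DESeq2 size factors (0.0463), library size alone (0.0205), upper quartile factors (0.0462), no count filter (0.0264) or the Paneth cell level as a covariate (0.0467). Of the proximal intestine genes 2, 1, 1, 1, 1 and 1 were lower in the same order. Single libraries decided the call of Fabp2 (control 3 or knockout 3; adjusted p up to 0.0693), Slc15a1 (control 2 or 3 or each knockout; adjusted p up to 0.133) and S100g (control 2 or 3 or each knockout; adjusted p up to 0.103).

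The proliferation list was called higher (median 0.41, camera adjusted p = 0.00065; adjusted p = 0.948 with an estimated correlation). Of its 42 genes 4 rose, near the share among all tested genes (1307 of 14005), and none of the 4 passed over the list alone. Ccnd1, which encodes cyclin D1 (0.74 ± 0.15), Cdt1, a replication licensing factor (0.66 ± 0.15), and Birc5 (0.66 ± 0.18) were among them, and Mki67 stood at 0.42 ± 0.30. Control 2, the library low in Paneth cell genes, was also lowest in this list, and without it the call was lost (adjusted p = 0.0568, 1 gene higher). The number of higher genes was 13 without control 1, 1 each without control 3, knockout 1 or knockout 2, and 0 without knockout 3. Of 21 stem cell genes the Wnt target Ephb2 rose (1.09 ± 0.30) and Rgmb fell (-0.46 ± 0.11), none over the list alone, while Nrn1 (-1.37 ± 0.47) and Slc12a2 (0.36 ± 0.34) did not pass the test. Among 25 genes of lineage choice and Notch signalling 2 rose and 4 fell, including Jag1, a Notch ligand (0.84 ± 0.17), and the intestinal transcription factors Hnf4g (-0.80 ± 0.13) and Cdx2 (-0.53 ± 0.11), with the related Hnf4a at -0.27 ± 0.13. In the list of the fetal-like regenerative state Ccnd2 rose (0.96 ± 0.13) and Cd55 fell (-1.38 ± 0.27) of 23 members, and Tinagl1 stood at -0.56 ± 0.17. Of 17 YAP targets Areg, an EGF receptor ligand, rose (1.04 ± 0.23), whereas Crim1 (-0.64 ± 0.09) and the related ligand Ereg (-0.79 ± 0.22) fell, and Wwc1 stood at -0.17 ± 0.12. Camera called none of these 4 lists (adjusted p = 0.842, 0.612, 0.146 and 0.63). Of the stem cell genes 1, 1, 0, 0, 0 and 0 were higher and 1, 0, 0, 0, 0 and 0 were lower without controls 1 to 3 and knockouts 1 to 3 in turn. Of the lineage and Notch genes 4, 1, 0, 1, 1 and 0 were higher and 6, 2, 1, 4, 1 and 1 were lower in the same order. Of the fetal-like state genes 2, 1, 1, 1, 1 and 1 were higher and 2, 1, 0, 1, 0 and 1 were lower in the same order. Fetal-like state genes were called lower as a list without control 2 (adjusted p = 0.0305) and with library size alone (0.0476). Of the YAP targets 2, 0, 1, 1, 0 and 0 were higher and 2, 1, 1, 1, 1 and 1 were lower in the same order. Leaving out 1 library ended the call of Ccnd1 (control 3 or knockout 3; adjusted p up to 0.0669), Cdt1 (control 2 or each knockout; adjusted p up to 0.0889), Birc5 (control 2 or 3 or each knockout; adjusted p up to 0.118) and Ephb2 (control 3 or each knockout; adjusted p up to 0.122). Without 1 library the test was not passed by Rgmb (control 2 or 3 or each knockout; adjusted p up to 0.117), Jag1 (control 3 or knockout 2 or 3; adjusted p up to 0.0700), Cdx2 (control 3 or knockout 2 or 3; adjusted p up to 0.0585) and Cd55 (control 3 or knockout 2; adjusted p up to 0.0646). The call was lost without 1 library for Areg (control 2 or knockout 2 or 3; adjusted p up to 0.0779) and Ereg (control 2 or 3 or each knockout; adjusted p up to 0.143).

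Components of the mTORC1 pathway moved in both directions, with 5 of 35 higher and 6 lower, or 6 and 6 over the list alone, and no call for the list (camera adjusted p = 0.882). Akt1s1, which encodes an inhibitory subunit, rose from 24.9 ± 2.28 to 52.2 ± 7.73 CPM (1.07 ± 0.14), and the S6 kinase gene Rps6kb1 rose too (0.82 ± 0.16). Slc38a9, a lysosomal amino acid sensor (-1.27 ± 0.19), and Deptor, another inhibitory component (-0.84 ± 0.14), fell, and Rps6 stood at -0.32 ± 0.15. Ribosome biogenesis genes rose, 16 of 31 with none lower, or 20 higher and 1 lower over the list alone (median 0.65, camera adjusted p = 6.5e-09; adjusted p = 0.948 with an estimated correlation). Pes1 (0.85 ± 0.10), Utp4 (1.47 ± 0.18) and Rrp12 (1.38 ± 0.18), which act in nucleolar processing of ribosomal RNA, were among them, and nucleolin, Ncl, stood at 0.32 ± 0.19. Their number was 8 without control 3 and 7 without knockout 3, 13 without control 2, and 24 without control 1. As in the proliferation list, control 2 was the lowest control (-0.33 log2 units relative to the control mean) and control 1 the highest (0.32). The knockout libraries stood at 0.50 to 0.70, and the rises of the proliferation and ribosome biogenesis lists were not tested apart. Of 76 cytosolic ribosomal protein genes 4 fell, a smaller share than among all tested genes (1312 of 14005), and none passed over the list alone. The list was called lower (median -0.24, camera adjusted p = 0.0101; adjusted p = 0.992 with an estimated correlation). Rpl7 (-0.68 ± 0.17), Rplp0 (-0.58 ± 0.15) and Rpl23a (-0.66 ± 0.17) fell and Rpl4 stood at -0.06 ± 0.14, and with library size alone none of the 76 passed. Without control 1 this median was 0.04, with 7 genes higher and 3 lower (adjusted p = 0.822), while 1 gene fell without control 3 and 0 without control 2 or any 1 of the knockout libraries. Of 32 genes of ATF4 and amino acid supply 4 rose and none fell, all charging enzymes of transfer RNA: Wars1 (1.03 ± 0.13), Sars1 (0.69 ± 0.11), Eprs1 (0.46 ± 0.10) and Gars1 (0.48 ± 0.12). Slc3a2 stood at 0.18 ± 0.25, and the list was not called (adjusted p = 0.326). Of the mTORC1 components 6, 4, 3, 3, 3 and 1 were higher and 4, 6, 3, 4, 3 and 3 were lower without controls 1 to 3 and knockouts 1 to 3 in turn. Of the amino acid supply genes 8, 3, 3, 3, 3 and 3 were higher in the same order. With 1 library left out, no call was made for Rps6kb1 (control 3 or knockout 3; adjusted p up to 0.0629), Rpl7 (control 2 or each knockout; adjusted p up to 0.106), Rplp0 (control 2 or 3 or each knockout; adjusted p up to 0.121) and Rpl23a (control 2 or 3 or each knockout; adjusted p up to 0.122). Calls that ended without 1 library were those of Eprs1 (knockout 2 or 3; adjusted p up to 0.0691) and Gars1 (control 2 or 3 or knockout 1 or 2; adjusted p up to 0.0988).

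Sterol synthesis genes fell, 8 of 25 with none higher, or 10 over the list alone (median -0.66, camera adjusted p = 0.00044; adjusted p = 0.948 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, went from 607 ± 30.5 to 233 ± 66.9 CPM (-1.38 ± 0.20), and Msmo1 (-1.54 ± 0.28) and the sterol carrier Stard4 (-0.72 ± 0.14) fell with it. The mean of the list in knockout 1 stood at -0.15 log2 units relative to the control mean, close to control 1 at -0.10, against -0.96 and -0.63 in the other knockout libraries. The number that fell was 5 without control 1, 4 without control 2, 3 without control 3, 14 without knockout 1, 4 without knockout 2 and 1 without knockout 3. Of 17 lipogenic genes Acly rose (0.50 ± 0.12) and malic enzyme Me1 fell (-2.12 ± 0.38), or 3 and 2 over the list alone, while Acsl3 (-1.64 ± 0.46) and Acsl5 (0.25 ± 0.21) did not pass the test. Glycolytic enzymes and HIF1 targets fell in 6 of 23 cases and rose in none, among them Bnip3 (-1.03 ± 0.13), enolase Eno1 (-0.78 ± 0.10) and aldolase Aldoa (-0.89 ± 0.12), with lactate dehydrogenase Ldha at 0.36 ± 0.14. Lysosome and autophagy genes went both ways, 7 of 31 higher and 5 lower, or 9 and 5 over the list alone. The proton pump subunit Atp6v1a rose (0.62 ± 0.10), whereas Map1lc3a (-1.37 ± 0.17) and Tfeb, a transcription factor of lysosomal genes (-1.25 ± 0.24), fell, and Lamp1 stood at 0.34 ± 0.16. Camera called none of these 3 lists (adjusted p = 0.967, 0.066 and 0.967). Of the lipogenic genes 3, 0, 0, 0, 1 and 0 were higher and 1, 2, 2, 1, 0 and 0 were lower without controls 1 to 3 and knockouts 1 to 3 in turn. Of the glycolytic and HIF1 genes 2, 0, 0, 0, 0 and 0 were higher and 5, 4, 3, 4, 3 and 3 were lower in the same order. Glycolytic and HIF1 genes were called lower as a list without control 2 (adjusted p = 0.0175) or knockout 1 (adjusted p = 0.0145) and with no count filter (0.0393) or the Paneth cell level as a covariate (0.0467). Of the lysosome and autophagy genes 8, 5, 4, 3, 2 and 3 were higher and 9, 4, 1, 4, 3 and 2 were lower in the same order. Single libraries decided the call of Msmo1 (knockout 3; adjusted p up to 0.0542), Stard4 (knockout 2 or 3; adjusted p up to 0.0590), Acly (control 2 or 3 or knockout 1 or 3; adjusted p up to 0.0840) and Me1 (knockout 2 or 3; adjusted p up to 0.0598). Leaving out 1 library ended the call of Tfeb (control 3 or knockout 3; adjusted p up to 0.0573).

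Nuclear genes of oxidative phosphorylation fell, 18 of 79 against 1 higher, or 20 and 1 over the list alone (median -0.17, camera adjusted p = 0.0021; adjusted p = 0.948 with an estimated correlation). Ndufa3, a complex I subunit, went from 18.8 ± 0.978 to 6.07 ± 0.793 CPM (-1.63 ± 0.16), and Cox7b (-0.72 ± 0.10), Atp5d (-0.67 ± 0.12) and Atp5b (-0.50 ± 0.12) fell by less. With library size alone the median was -0.04 with 9 lower and 4 higher. Without control 1 the call was lost (adjusted p = 0.0749, 14 lower), and 7 genes fell without control 2, 6 without control 3, and 4 each without knockout 2 or knockout 3. Of 26 genes of fatty acid oxidation and PPARA targets 4 rose and 4 fell, or 6 and 6 over the list alone (camera adjusted p = 0.842). Acadvl, a long-chain acyl-CoA dehydrogenase (-1.33 ± 0.13), and the coactivator Ppargc1a (-1.34 ± 0.23) fell, and Eci1 rose (0.71 ± 0.12). Of the oxidative phosphorylation genes 3, 1, 0, 0, 0 and 0 were higher without controls 1 to 3 and knockouts 1 to 3 in turn. Of the fatty acid oxidation genes 5, 2, 1, 2, 1 and 1 were higher and 3, 4, 4, 2, 2 and 2 were lower in the same order. Without 1 library the test was not passed by Atp5b (control 2 or 3 or each knockout; adjusted p up to 0.112).

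Interferon response genes fell, 8 of 39 with none higher, or 11 over the list alone (median -0.4, camera adjusted p = 0.0033; adjusted p = 0.948 with an estimated correlation). Parp14 went from 173 ± 13.2 to 78.8 ± 1.99 CPM (-1.13 ± 0.10), the antiviral GTPase Mx1 (-2.63 ± 0.35) and the transcription factor Irf1 (-0.80 ± 0.12) fell too, and Ifi27l2b stood at -0.74 ± 0.31. Without knockout 2 or knockout 3 the number was 5. None of 8 genes of MHC class II presentation changed, with Ciita at -0.51 ± 0.29, H2-DMb2 at -0.67 ± 0.64, H2-Eb1 at -0.24 ± 0.25 and Cd74 at -0.09 ± 0.24. At an unadjusted p under 0.05, 0 of them passed edgeR, and 0 passed DESeq2 after adjustment. Of 23 antimicrobial and inflammatory genes 2 rose and 4 fell, or 3 and 4 over the list alone. The hydrogen peroxide-producing oxidase Duox2 went from 460 ± 185 to 112 ± 37.9 CPM (-2.04 ± 0.36), Tnfaip3, a brake on NF-κB, fell (-1.10 ± 0.18), the chemokine Ccl28 rose (0.94 ± 0.21) and Reg3b stood at 0.62 ± 0.51. Among 25 unfolded protein response genes 7 rose and 2 fell, or 11 and 2 over the list alone. The endoplasmic reticulum proteins Sdf2l1 (1.16 ± 0.17) and Dnajb11 (0.73 ± 0.13) rose, the stress sensor Eif2ak3 fell (-0.91 ± 0.17) and Hsp90b1 stood at 0.12 ± 0.14. Camera did not call these 3 lists (adjusted p = 0.744, 0.842 and 0.0593). Of the interferon response genes 0, 1, 0, 0, 0 and 0 were higher without controls 1 to 3 and knockouts 1 to 3 in turn. Of the antimicrobial and inflammatory genes 2, 3, 0, 0, 3 and 0 were higher and 5, 2, 3, 2, 2 and 1 were lower in the same order. Of the unfolded protein response genes 9, 4, 3, 4, 3 and 6 were higher in the same order. Unfolded protein response genes were called higher as a list without control 2 (adjusted p = 0.0484) or knockout 3 (adjusted p = 0.00749) and with library size alone (0.0459), upper quartile factors (0.0470) or no count filter (0.0296). The call was lost without 1 library for Duox2 (knockout 3; adjusted p up to 0.0538) and Ccl28 (control 2 or 3 or knockout 1 or 3; adjusted p up to 0.0859).

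Of 22 p53 targets 3 rose and 2 fell, including the death receptor Tnfrsf10b (1.41 ± 0.28), Pmaip1 (-0.78 ± 0.15) and Sesn1 (-0.53 ± 0.10), with Perp at -0.30 ± 0.18. Of 29 cell death genes 1 rose and 7 fell, among them the 3 gasdermin C genes above, the survival factors Bcl2l1 (-0.65 ± 0.12) and Mcl1 (-0.53 ± 0.14) and the adaptor Fadd (-0.70 ± 0.14). Among 25 junction genes plakoglobin, Jup, fell (-0.67 ± 0.11), while Dsp (-0.64 ± 0.21), Pkp3 (-0.32 ± 0.11) and Epcam (-0.47 ± 0.18) did not pass the test. Hcfc1, a chromatin cofactor that OGT cleaves, rose from 62.9 ± 6.62 to 181 ± 14.0 CPM (1.53 ± 0.12). Of the 18 genes in its list of chromatin partners the acetyltransferase Kat8 also rose (0.86 ± 0.20), and Tet3 (-0.43 ± 0.11) and 1 other gene fell, or 8 higher and 5 lower over the list alone. Early stress genes, which rise during tissue dissociation, were lower in 4 of 23 cases and higher in 1, or 5 and 1 over the list alone, with Klf6 at -1.23 ± 0.18, Egr1 at -1.92 ± 0.38 and Dnajb1 at -0.69 ± 0.16. Camera called none of these 5 lists (adjusted p = 0.931, 0.259, 0.137, 0.414 and 0.137). Of the p53 targets 3, 1, 1, 2, 2 and 1 were higher and 2, 2, 2, 2, 1 and 0 were lower without controls 1 to 3 and knockouts 1 to 3 in turn. Of the cell death genes 0, 2, 0, 0, 0 and 0 were higher and 4, 4, 3, 6, 2 and 2 were lower in the same order. Of the junction genes 1, 1, 0, 0, 0 and 0 were higher and 1, 2, 1, 2, 1 and 1 were lower in the same order. Junction genes were called lower as a list without knockout 1 (adjusted p = 0.0145). Of the chromatin partner genes 5, 2, 1, 2, 1 and 1 were higher and 3, 0, 0, 0, 0 and 0 were lower in the same order. Of the early stress genes 1, 0, 0, 0, 0 and 1 were higher and 6, 2, 2, 2, 2 and 1 were lower in the same order. Early stress genes were called lower as a list without knockout 2 (adjusted p = 0.0356). With 1 library left out, no call was made for Pmaip1 (knockout 3; adjusted p up to 0.0542), Sesn1 (knockout 2 or 3; adjusted p up to 0.0547), Mcl1 (control 2 or 3 or knockout 2 or 3; adjusted p up to 0.127) and Fadd (control 3 or knockout 2 or 3; adjusted p up to 0.0661). Calls that ended without 1 library were those of Kat8 (control 3 or knockout 2 or 3; adjusted p up to 0.0948), Tet3 (control 2 or 3 or each knockout; adjusted p up to 0.105), Egr1 (knockout 2 or 3; adjusted p up to 0.0717) and Dnajb1 (control 2 or 3 or knockout 1 or 3; adjusted p up to 0.0889).

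Markers of other cells that an epithelial isolate can hold were mostly not past the test. Of 20 lymphocyte genes Trdc rose (0.99 ± 0.27) and Gzma stood at 0.21 ± 0.41, and none of 14 B and plasma cell genes passed, with Tnfrsf17 at 0.54 ± 0.48 and Igha at 0.18 ± 0.55. The B and plasma cell list of knockout 1 stood at -2.26 log2 units relative to the control mean. Of 17 myeloid genes Siglecf fell, with Lyz2 at -0.30 ± 0.14. Fibroblast genes rose in 2 of 16 cases, Col1a2 among them (0.58 ± 0.12), with Dcn at 0.09 ± 0.22, and among 13 endothelial genes Lyve1 rose (1.47 ± 0.20) and Plvap stood at 0.25 ± 0.35. The smooth muscle list was called lower with no member past the test (median -0.66, camera adjusted p = 0.0386; adjusted p = 0.948 with an estimated correlation). Smtn stood at -0.71 ± 0.28 and Myh11 at -0.64 ± 0.40, and the call was lost without control 2, control 3 or knockout 1 (adjusted p = 0.116, 0.12 and 0.16), while 6 members fell without control 1. Of 13 enteric neuron and glia genes Vip rose (1.13 ± 0.30) and 3 fell, including Ret (-0.88 ± 0.18). None of 4 red blood cell genes, 2 pancreatic acinar genes or 9 genes of fat and mesothelium passed, with Hba-a1 at 0.25 ± 0.47, Hbb-bs at -0.16 ± 0.63, Cela1 at -0.43 ± 0.29, Clps at -0.41 ± 0.85, Upk3b at -1.63 ± 0.61 and Fabp4 at 28.7 ± 21.5 CPM in control and 14.4 ± 3.08 CPM in knockout libraries. Y-linked genes were present in all 6 libraries, Uty lower in knockout (-0.51 ± 0.13) and Eif2s3y at -0.17 ± 0.11. Xist, also planned for this check of sex, had no match by name, so female cells within a library cannot be excluded. The 13 mitochondrial transcripts were called lower as a list with no member past the test (median -0.36, camera adjusted p = 0.0258; adjusted p = 0.948 with an estimated correlation). The transcripts mt-Nd4 (-0.56 ± 0.17) and mt-Co1 (-0.36 ± 0.22) did not pass, and the call was lost without control 1, control 3 or knockout 2 (adjusted p = 0.0641, 0.0534 and 0.184) and without the 20 most abundant genes (0.182). Of the lists with no gene past the test, edgeR gave an unadjusted p under 0.05 to 0 B and plasma cell genes, 3 smooth muscle genes, 0 red blood cell genes, 0 pancreatic genes, 1 gene of fat and mesothelium and 6 mitochondrial transcripts, and DESeq2 called 0, 2, 0, 0, 1 and 6 of them. Where no count over the list alone is given above, it equalled the count over all genes, except in the lymphocyte list, where it was 0. The estimated counts of Lyz1, Eno1, Rpl23a, Acadvl, Pgm3, Ccnd1, H2-DMb2, Lyz2, Hba-a1 and Hbb-bs were not whole in any library, so reads shared with similar genes enter their values. Those of Lamp1 were not whole in 5 libraries and those of Cd55 in 4. The other lists of this paragraph had camera adjusted p between 0.137 and 0.967. Of the lymphocyte genes 0, 0, 0, 0, 1 and 0 were higher without controls 1 to 3 and knockouts 1 to 3 in turn. Of the myeloid genes 1, 1, 1, 2, 1 and 1 were lower in the same order. Of the fibroblast genes 2, 3, 2, 2, 2 and 0 were higher and 2, 0, 0, 0, 0 and 0 were lower in the same order. Endothelial genes were called higher as a list without control 2 (adjusted p = 0.00605). Of the neuron and glia genes 0, 0, 1, 1, 0 and 0 were higher and 4, 1, 0, 1, 1 and 0 were lower in the same order. Neuron and glia genes were called lower as a list without control 1 (adjusted p = 0.0252) and with library size alone (0.0476). Of the fat and mesothelium genes 1, 0, 4, 0, 0 and 0 were lower in the same order. Fat and mesothelium genes were called lower as a list without control 3 (adjusted p = 0.00148). Of the Y-linked genes 0, 0, 0, 0, 0 and 0 were lower in the same order. Of the mitochondrial transcripts 1, 1, 0, 1, 0 and 0 were lower in the same order. Single libraries decided the call of Trdc (each control or knockout 1 or 3; adjusted p up to 0.125), Col1a2 (knockout 3; adjusted p up to 0.0598), Vip (control 1 or 2 or knockout 2 or 3; adjusted p up to 0.123) and Ret (control 3 or knockout 3; adjusted p up to 0.0660). Leaving out 1 library ended the call of Uty (each control or each knockout; adjusted p up to 0.115).

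**Figure D4:**
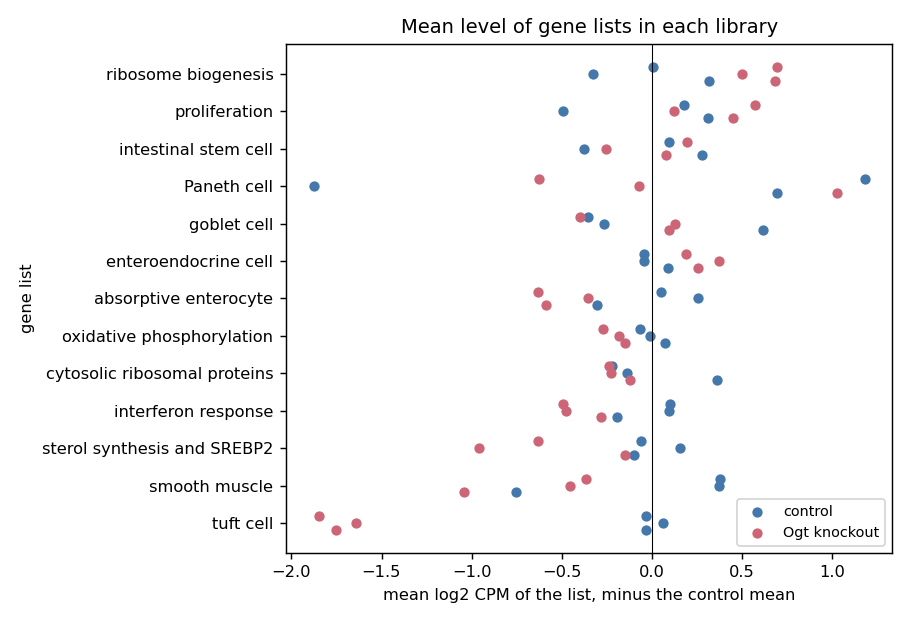
Mean log2 CPM of 13 gene lists in each library, minus the mean of the 3 control libraries; points are libraries, blue for control and red for Ogt knockout. Tuft cell values lie apart between the groups, whereas Paneth cell values range from -1.88 to 1.18 within the control group alone.

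On the first principal component of all tested genes, which held 45.6% of the variance, the 3 control libraries lay between -40.2 and -26.6 and the 3 knockout libraries between 28.2 and 45.0. The second component held 23.3% and ran within both groups, from control 2 at -23.9 to control 1 at 44.4.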

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

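The alternatives were planned before the data were examined, except the Paneth cell covariate and limma on log2(FPKM + 1). Ogt kept its direction and its call under all 22 alternatives, with a log2 fold change between -1.74 and -1.39. Among the 183 genes named, no called gene changed direction under any alternative that tested it. Some alternatives, such as the minimum of 5 FPKM, did not test all of these genes. Of the 129 called genes 71 kept their call without each library in turn and 58 lost it at least once.

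Leaving out 1 library gave between 1010 and 3305 changed genes, 549 to 1933 higher and 461 to 1372 lower, and between 8 and 12 list calls. Fewer samples were then tested, yet the count rose from 2619 to 3305 without control 1. The smaller number of samples alone therefore does not account for the range. With library size alone 2045 genes were higher and 859 lower, since the TMM factors of the knockout libraries are the larger ones. The FPKM values gave 1946 higher and 738 lower genes with a pseudocount of 1, 1906 and 724 with 0.1, and 1891 and 717 with 0.01. At a minimum of 5 FPKM the numbers were 1769 and 598. FPKM values are scaled by library total, and the median log2 fold change was 0.10 to 0.13 in these fits. That is near the 0.09 with library size alone, and other causes were not tested. A log2 fold change of at least 1 left 716 genes, 270 higher and 446 lower, by construction. Camera with an estimated correlation called 0 lists and fry, which does not compare a list with other genes, called 1, the tuft cell list. The first principal component held 41.3% of the variance of the 500 most variable genes.

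The replicate numbers did not meet the rule for pairing, since same-numbered libraries correlated at 0.27, 0.25 and 0.08 in their deviations from the group means, although each library correlated best with its own number. The replicate block gave 3401 changed genes in place of 2619 and 15 list calls in place of 9, all 9 included. The other 6 were enterocyte (adjusted p = 0.0309), fetal-like (0.0169), glycolysis (0.0402), junction (0.0458) and neuron and glia genes (0.0453), called lower, and unfolded protein response genes (0.0402), called higher. With the block the proliferation list had 16 higher genes and 1 lower in place of 4 and 0, and the number lower was 7 in place of 0 for smooth muscle, 11 in place of 4 for cytosolic ribosomal proteins, 6 in place of 1 for fetal-like genes and 7 in place of 1 for junction genes. The self-test, with 200 genes changed, recovered 55 of 100 genes changed 2-fold, so smaller changes can be missed. The real comparison called 2619 genes, so the recovered share need not be the same there.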

Other observations

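The gene groups of this and the next paragraph, and every test below except those on skeletal muscle genes and on the neighbours of Olfm4, were chosen after the results had been seen. Camera p-values of these groups describe the same data that prompted the choice and are no independent test. Of 78 measured genes of the mitochondrial ribosome, which translates the mitochondrial transcripts, 39 rose and 3 fell in Ogt knockout libraries, or 42 and 3 when adjusted over the list alone, with a median log2 fold change of 0.43 (0.56 with library size alone; camera adjusted p = 1.2e-11 over 6 such groups; adjusted p = 0.351 with an estimated correlation). Mrps7 rose from 25.2 ± 1.12 to 61.6 ± 3.89 CPM (1.29 ± 0.10) and Mrps18b from 20.1 ± 3.31 to 54.7 ± 1.83 CPM (1.45 ± 0.14), while Mrpl24 fell (-1.52 ± 0.14). Of 17 aminoacyl-tRNA synthetases picked by a name pattern, which leaves out Eprs1 and others, 7 rose and 1 fell (9 and 1 over the list alone; camera adjusted p = 7.1e-05; adjusted p = 0.149 with an estimated correlation). Rars rose from 106 ± 10.5 to 216 ± 7.93 CPM (1.02 ± 0.11), and Qars fell (-0.49 ± 0.11). tRNA methyltransferases rose in 5 of 16 cases and fell in 1 (8 and 1 over the list alone; camera adjusted p = 0.00048; adjusted p = 0.225 with an estimated correlation), with Trmt10a going from 3.93 ± 0.411 to 23.6 ± 1.54 CPM (2.58 ± 0.15). Among 6 gasdermin genes 3 fell and 1, Gsdma, rose (1.61 ± 0.41), without a call for the group (camera adjusted p = 0.237). The estimated counts of Mrpl24 were not whole in any library, so reads shared with similar genes enter its value. Of the mitochondrial ribosome genes 45, 32, 27, 28, 24 and 24 were higher without controls 1 to 3 and knockouts 1 to 3 in turn. Of the aminoacyl-tRNA synthetases 1, 0, 1, 1, 0 and 0 were lower in the same order. Of the tRNA methyltransferases 8, 5, 4, 4, 4 and 4 were higher and 1, 0, 1, 0, 0 and 0 were lower in the same order. Of the gasdermins 1, 0, 0, 1, 0 and 0 were higher and 1, 2, 2, 3, 1 and 1 were lower in the same order. Without 1 library the test was not passed by Qars (control 2 or knockout 2 or 3; adjusted p up to 0.0780) and Gsdma (control 2 or 3 or knockout 2 or 3; adjusted p up to 0.114).

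In the genes of the circadian clock, 2 of 9 output and period genes fell, Dbp (from 30.5 ± 13.2 to 7.62 ± 1.28 CPM) and Tef (-1.04 ± 0.28), or 5 over the list alone (median -0.97, camera adjusted p = 0.0099; adjusted p = 0.375 with an estimated correlation). Of 6 genes of the opposite phase Cry1 rose (0.64 ± 0.15), or 2 over the list alone, without a call for the group (camera adjusted p = 0.237). A candidate explanation is a different time of day of collection, which the labels do not give. Output minus opposite-phase level differed by -1.04 log2 units between the groups, and ranged over 1.46 units among the controls alone: control 1 stood at -1.17, near the knockout libraries at -1.51 to -1.22, against -0.15 and 0.29 in the other controls. These values may reflect collection at different hours within the control group, and an effect of the genotype on the clock stays open. Whether a difference in hour also enters the other changed genes was not tested. The number of changed genes rose from 2619 to 3305 without control 1. Estimated counts of Dbp were likewise not whole in any library. Of the clock output genes 8, 1, 1, 1, 1 and 0 were lower without controls 1 to 3 and knockouts 1 to 3 in turn. Of the opposite-phase clock genes 2, 0, 0, 0, 0 and 0 were higher in the same order. The call was lost without 1 library for Dbp (knockout 3; adjusted p up to 0.0554), Tef (control 2 or 3 or each knockout; adjusted p up to 0.140) and Cry1 (control 2 or 3 or each knockout; adjusted p up to 0.0787).

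For the lower tuft cell genes, the list median was -2.16 with TMM factors and -2.02 with library size alone. This change of scaling moved the median of all genes only from -0.05 to 0.09. The choice between these scalings therefore could not account for the fall, and the comparison could not have come out otherwise. A lower yield of goblet and enteroendocrine cells along with tuft cells would lower their genes too, but the joint median of these 43 genes was 0.16, with quartiles of -0.23 and 0.45. Paneth cell genes were not part of that test: their median was -0.15, and -0.60 without control 2, so a lower yield of Paneth cells stays open. A loss of tuft cells and a lower level of these transcripts per cell may each account for it and were not tested apart.

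For the higher muscle-type genes, Acta1 rose by 380 CPM together with Myot, Myl7 (2.39 ± 0.24) and Srl (1.86 ± 0.29), named here after their values were seen. Skeletal muscle cells would bring their other abundant transcripts, but the median rise of 8 such genes, with the test set before their values were seen, was 0% of the Acta1 rise. Ckm stood at 7.15 CPM in control and 3.85 CPM in knockout libraries, and Mylpf, the exception, rose from 1.1 to 3.25 CPM (adjusted p = 0.0128). Smooth muscle of the gut wall was argued against by the lower median of its list, -0.66. Expression in epithelial cells, or in a cell type not listed here, may account for the rise and was not tested. With 1 library left out, no call was made for Mylpf (knockout 2; adjusted p up to 0.0502).

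It was also tested whether a region of another strain, carried along with the Olfm4-CreER driver, could hold the changed genes. Both groups carry the floxed Ogt allele, so genes near Ogt cannot show such a region. Of the 50 tested genes nearest to Olfm4 in the order of GENCODE M21 24% had changed, at percentile 83.5 of all such windows, whose median was 18%. The Olfm4 value lay between the bounds set before the test, a 75th percentile of 22% and a 95th of 28%, so the test decided nothing there.

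The 6 libraries can be split into 2 groups of 3 in 10 ways. The real split called 2619 genes and the highest of the other 9 called 0, so 1 split reached the real count, and 10 splits are too few for a share under 0.05.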
